A study of Mus musculus with 2 samples.

How the data were processed

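Dimethylation of histone H3 at lysine 4 (H3K4me2), a modification found at promoters and at distal regulatory elements, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the hindbrain of mouse embryos at embryonic day 13.5, from strain B6NCrl. The labels describe 1 group of 2 replicates taken as separate biological samples, each from pooled embryos of both sexes. There was no other tissue, stage or treatment, so the comparison between samples is of the replicates with each other, and every other comparison sets genes or regions against other genes or regions of the same samples. The analysis used 4 deposited peak lists on assembly mm10, per the file headers: the list of each replicate, a list called on both replicates pooled, and a list of replicated peaks derived from the other 3. The peak caller, its settings and the rule for keeping a replicated peak are not given in the sources used here. The labels name a possible control experiment. It was not analysed here, nor were signal tracks.

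Each peak carries a fold enrichment, a ratio over control or background that the authors deposited. Each peak also carries the −log10 of its p-value and of its q-value, as deposited by the authors. The fold of a peak is the authors' own value and was used only to describe, rank or filter peaks within a list. The lists also give the position of each peak's summit. The lists hold no read counts, so the sequencing depth of each replicate is unknown, and no interval that needs depth is given. Depth and the caller's threshold set how many weak peaks a list holds, so the absence of a peak does not show that the modification is absent.

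Genes were taken from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. None of the peaks (0) lay beyond the end of its chromosome in the GRCm38 reference. The 21853 protein-coding genes on 21 chromosomes (the autosomes, X and Y) were used, and peaks on other contigs were left out. A promoter was marked when a replicated peak lay within 1 kb of a transcription start site (TSS) of any protein-coding transcript of the gene. Peaks separated by gaps of up to 1 kb were merged into a domain. The promoter domain length of a gene is the length of the longest domain that reached 1 of its promoters, or 0. This length is the authors' peak width joined over short gaps, so it depends on where the caller split a region. A distal peak lay over 2 kb from every TSS of a protein-coding transcript and was assigned to the gene with the nearest such TSS, which is a position and not a known target. Promoters of non-coding genes can therefore count as distal peaks. For bases covered by peaks, the annotation classes were, in order of priority, promoter (within 1 kb of a TSS), other exon, intron and intergenic, and percentages were taken over the 2648 Mb of assembled bases.

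Overlap of the lists (at least 1 bp) and the location of peaks were set against 100 circular shifts of the peaks along chromosomes with assembly gaps removed. The smallest p these can give is 0.0099 for an overlap and 0.0198 for the two-sided test of location. The 24 gene lists were fixed before the data were examined. They held regional regulators of the hindbrain and forebrain, neuronal and glial genes, other cell types that a dissected hindbrain could hold, and genes of other tissues. Of 338 listed symbols 337 were found, Ahsp being the exception, and 1463 olfactory and vomeronasal receptor genes were found by their prefixes. Marked promoters of a list were compared with those of all other genes by Fisher's exact test, two-sided. Domain lengths and numbers of distal peaks were compared by the mean rank percentile of the members against 100000 random lists of the same size, a two-sided permutation test whose smallest p is 1e-05. All 3 sets of p-values were adjusted over the 24 lists by the Benjamini-Hochberg method, with a threshold of 0.05. The means of 2 groups of genes were compared by two-sided permutation tests with 100000 resamples, whose smallest p is 2e-05, and 95% intervals of differences came from 10000 bootstrap resamples of the genes. Genes are not independent replicates, and neighbouring genes can share a domain, so these tests compare genes within these 2 libraries and do not measure variation between embryos. On simulated data, 5.2% of 1000 random lists of 14 genes gave p under 0.05 in the rank test, as did 83% of 200 lists with 11 of 14 members drawn from the upper part of the ranking. In the Fisher test 5.5% of 1000 random lists did.

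Genes were named by a rule fixed in advance: the 20 genes with the longest promoter domains, the 4 members of each list with the longest domains and unmarked members where there were 5 or fewer, all Hox genes by paralog group, the 10 replicated peaks of highest fold, the 5 genes per replicate marked in that list alone with the highest fold, and the 10 genes with the most distal peaks. Other genes, among them regulators with short domains or weak peaks, were named as examples after the data were seen. Values are given for the replicated list. The mean and SD over both replicates' own lists are added for main values and for named genes whose length differed over 1.5 times between the lists. Alternatives were other peak lists (each replicate alone, pooled), −log10 q of at least 2 or 10, other overlaps, other TSS windows and the annotated 5′ end of each gene alone, no merging or gaps of up to 3 kb, other backgrounds, and other rules for distal peaks. Counting a shared Hox domain once within its group and leaving out Hoxb9 were added after the data were seen. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.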

Results

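H3K4me2 was profiled by ChIP-seq in 2 biological replicates of mouse hindbrain at embryonic day 13.5, the stage at which the cerebellar primordium, pons and medulla are generating neurons. The replicate lists held 49784 and 50629 peaks, a mean of 50207 ± 598 (SD, n = 2), and covered 55.3 ± 0.462 Mb, or 2.09% ± 0.0175 of the assembled genome. The replicated list held 38114 peaks of a median width of 1055 bp and covered 58.9 Mb, 2.22% of the assembled bases. Sequencing depth is unknown from these lists.

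The first comparison asked how far the 2 replicates marked the same places. They shared most of their peaks: 80.4% of the 49768 replicate 1 peaks on the chromosomes overlapped a replicate 2 peak, and 79.5% of 50613 did so in the other direction, against means of 3.99% and 3.95% in shifted lists (permutation p = 0.0099 for both, the smallest that 100 shifts can give). The bases covered by both lists were 0.786 of those covered by either, against 0.0117 after shifting. Across 40042 matched peaks the authors' folds had a Spearman's rho of 0.835, a description across peaks, which are not independent replicates. The 9726 and 10351 unshared peaks were narrow and weak. Their median widths were 226 and 232 bp, against 881 and 892 bp for shared peaks, and they held 4.53% and 4.94% of the covered bases. With at least 50% of both peaks required to overlap, 64.5% of replicate 1 peaks were shared.

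At promoters the replicates differed at few genes. Both lists marked 14556 protein-coding genes, 128 were marked in replicate 1 alone, 108 in replicate 2 alone and 7061 in neither. Over the genes marked in both, domain length had a rho of 0.943 between replicates, across genes. At the genes marked in a single list most peaks were weak, with a median fold of 3.31 in replicate 1 and 3.24 in replicate 2. Of the genes marked in replicate 1 alone, those of highest fold were Igflr1 (25.4), Gm26602 (15.1), the neutrophil proteinase Prtn3 (7.44), Papolb (6.06) and 3425401B19Rik (5.74). Those of replicate 2 were 1700086D15Rik (35.1), Cby3 (30.1), the anti-Müllerian hormone gene Amh (29.95), the apolipoprotein gene Apoa1 (23.3) and Nudt11 (14.8). Of the genes marked in a single list, 28 of 128 and 28 of 108 had a peak of the other list within 2.5 kb of a TSS.

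The replicated list kept 38099 of the 51138 pooled peaks on the chromosomes, 74.5% of the peaks and 94.3% of their bases, all with unchanged coordinates. Of the kept peaks 95.9% overlapped a replicate 1 peak and 96.6% a replicate 2 peak. Some replicated peaks thus had no counterpart in the list of 1 replicate. Of the dropped peaks 34.0% and 37.4% overlapped a peak of these lists. The 13039 dropped peaks had a median width of 242 bp and a median fold of 2.67, against 1055 bp and 11.3 for kept peaks. Of the dropped peaks 7.51% lay within 1 kb of a TSS, against 44.4% of the kept ones, so the difference between the lists was mostly among weak peaks away from promoters.

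H3K4me2 was concentrated at gene starts. Promoters made up 44.9% of the bases covered by replicated peaks (45.97% ± 0.476, SD, n = 2, in the replicate lists) and 2.44% of the assembled genome, a ratio of 18.4, and no shifted list exceeded 3.51%. Other exons held 4.12% of covered bases, a ratio of 1.77, introns 32.4%, a ratio of 0.924, and intergenic sequence 18.6%, a ratio of 0.309. Each class differed from the shifted lists (permutation p = 0.0198, two-sided, the smallest possible). The promoter ratio fell to 11.8 with a TSS window of 2.5 kb. With that window the exon ratio was 1.01, with 2.08% of covered bases against a mean of 2.24% in shifted lists (permutation p = 0.0792), and the intron ratio was above 1 with narrower promoters, at 1.22 within 500 bp. Among 14926 summits within 2 kb of a gene's 5′ end, 76.4% lay downstream of it, with a median offset of 439.5 bp, and 14.6% lay within 200 bp. This end is the outermost annotated one, so other TSSs of a gene lie downstream of it by definition, which can add to the excess.

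**Figure D1:**
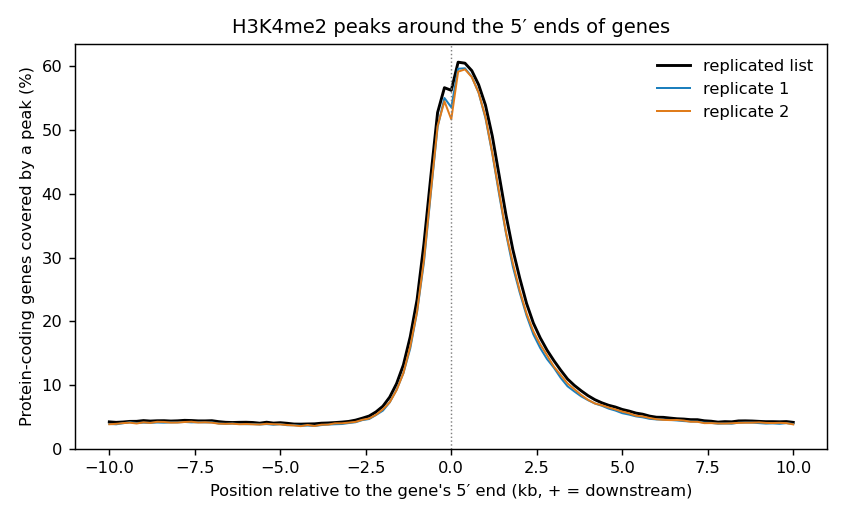
Percentage of protein-coding genes (y axis) covered by an H3K4me2 peak at each position from 10 kb upstream to 10 kb downstream of the gene's annotated 5′ end (x axis, kb), for the replicated list and each replicate. Coverage is asymmetric: at 2000 bp downstream 26.8% of genes were covered in the replicated list, and at 2000 bp upstream 6.68%. Other TSSs of a gene lie downstream of its 5′ end by definition, which can add to the asymmetry.

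The peaks with the highest authors' fold all lay at a TSS. They were at Adgrg6, an adhesion receptor needed for Schwann cell myelination (fold 82.0, chromosome 10, 14543889 to 14546507), at the transcription factor genes Klf15 (77.2), E2f8 (76.4), Egr1 (75.6) and E2f2 (73.4), at Kmt2d, which encodes a histone H3 lysine 4 methyltransferase (73.8), and at Ipo13 (73.7), Col27a1 (73.1), the BMP pathway gene Smad9 (72.6) and Ism1 (71.9). In the replicate lists the Adgrg6 peak had folds of 74.6 and 67.5. In all, 14625 of 21853 protein-coding genes were marked (66.9%; 67.1% ± 0.0647 in the replicate lists), and the median domain at a marked promoter was 2.83 kb, with quartiles of 2.03 and 3.98 kb.

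Of the 20 genes with the longest promoter domains, 15 were Hox genes. A domain of 85.8 kb (85.7 ± 0.0184 kb in the replicate lists) covered the HoxB cluster from Hoxb9 to Hoxb2 on chromosome 11, from 96270850 to 96356676. A domain of 58.3 kb on chromosome 6, from 52155690 to 52214013, reached Hoxa1 to Hoxa6 and the predicted genes 5730596B20Rik and Gm28308 (60.5 ± 3.09 kb at these genes in the replicate lists). Next came the 39.0 kb shared by Zic1 and Zic4, zinc finger genes of the dorsal hindbrain, on chromosome 9 (91349862 to 91388898), the 37.3 kb at the orphan nuclear receptor gene Nr2f1 and the 33.4 kb at Hoxc4, which also reached Hoxc5 and Hoxc6. Zic1, Zic4 and Nr2f1 were less even between replicates, because replicate 1 divided the domain: 31.6 ± 10.5 kb for the Zic pair and 31.4 ± 8.89 kb for Nr2f1 (SD, n = 2). Of 30745 domains, 219 were 10 kb or longer.

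Within the Hox clusters, whose paralog groups 1 to 4 are expressed in the hindbrain, the mark covered the low-numbered genes and was sparse over the high-numbered ones. All 12 genes of groups 1 to 4 and all 11 of groups 5 to 8 were marked, against 7 of 16 in groups 9 to 13. Mean domain length was 47.6 kb in groups 1 to 4 and 5.68 kb in groups 9 to 13, a difference of 41.97 kb (95% interval 21.3 to 60.5 kb, two-sided permutation p = 0.00062). The bases covered within 2 kb of any TSS of a gene were 6.05 kb per gene against 0.475 kb (permutation p = 2e-05, the smallest possible), with medians of 4.00 and 0.09 kb. The windows of all TSSs of a gene were joined, and the sum was not divided by their length. It can thus also rise with the number of annotated TSSs. Low-numbered genes were not all under long domains: Hoxb1 had 1.71 kb (1.63 ± 0.0997 kb in the replicates) and Hoxd1 1.97 kb, while Hoxd3 and Hoxd4 shared 22.0 kb.

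In groups 5 to 8, Hoxb5, Hoxb6, Hoxb7 and Hoxb8 lay under the HoxB domain and Hoxa5 and Hoxa6 under the HoxA domain, while Hoxc8 had 0.574 kb and Hoxd8 2.25 kb (3.02 ± 1.06 kb in the replicates). Hoxa7 had 2.91 kb in the replicated list and 33.1 ± 41.8 kb in the replicates, since the replicate 1 list joined it to the domain of Hoxa1 to Hoxa6. In groups 9 to 13 the single long domain was that of Hoxb9. Hoxd9 (1.30 kb), Hoxa13 (1.105 kb; 0.78 ± 0.464 kb), Hoxc13 (0.986 kb; 0.646 ± 0.323 kb), Hoxd13 (0.83 kb), Hoxc10 (0.488 kb; 0.375 ± 0.129 kb) and Hoxa10 (0.285 kb; 0.19 ± 0.00636 kb) carried short peaks. Hoxa9, Hoxa11, Hoxb13, Hoxc9, Hoxc11, Hoxc12, Hoxd10, Hoxd11 and Hoxd12 had no promoter peak in the replicated list, although the replicate 1 list had short ones at Hoxb13, Hoxd10 and Hoxd11. Short replicated peaks with folds of 3.77 and 5.89 lay inside Hoxc9, away from its promoter. Neighbouring Hox genes share domains, so the genes are not independent. Counting a shared domain once within its group left 6 domains against 16 genes, with unmarked genes as 0 and the HoxB domain in both groups, and gave a difference of 28.2 kb (exact permutation p = 0.0479). In the other checks single peaks without merging gave 23.8 kb (p = 2e-05), and leaving out Hoxb9 gave 47.3 kb (p = 2e-05), both by permutation.

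**Figure D2:**
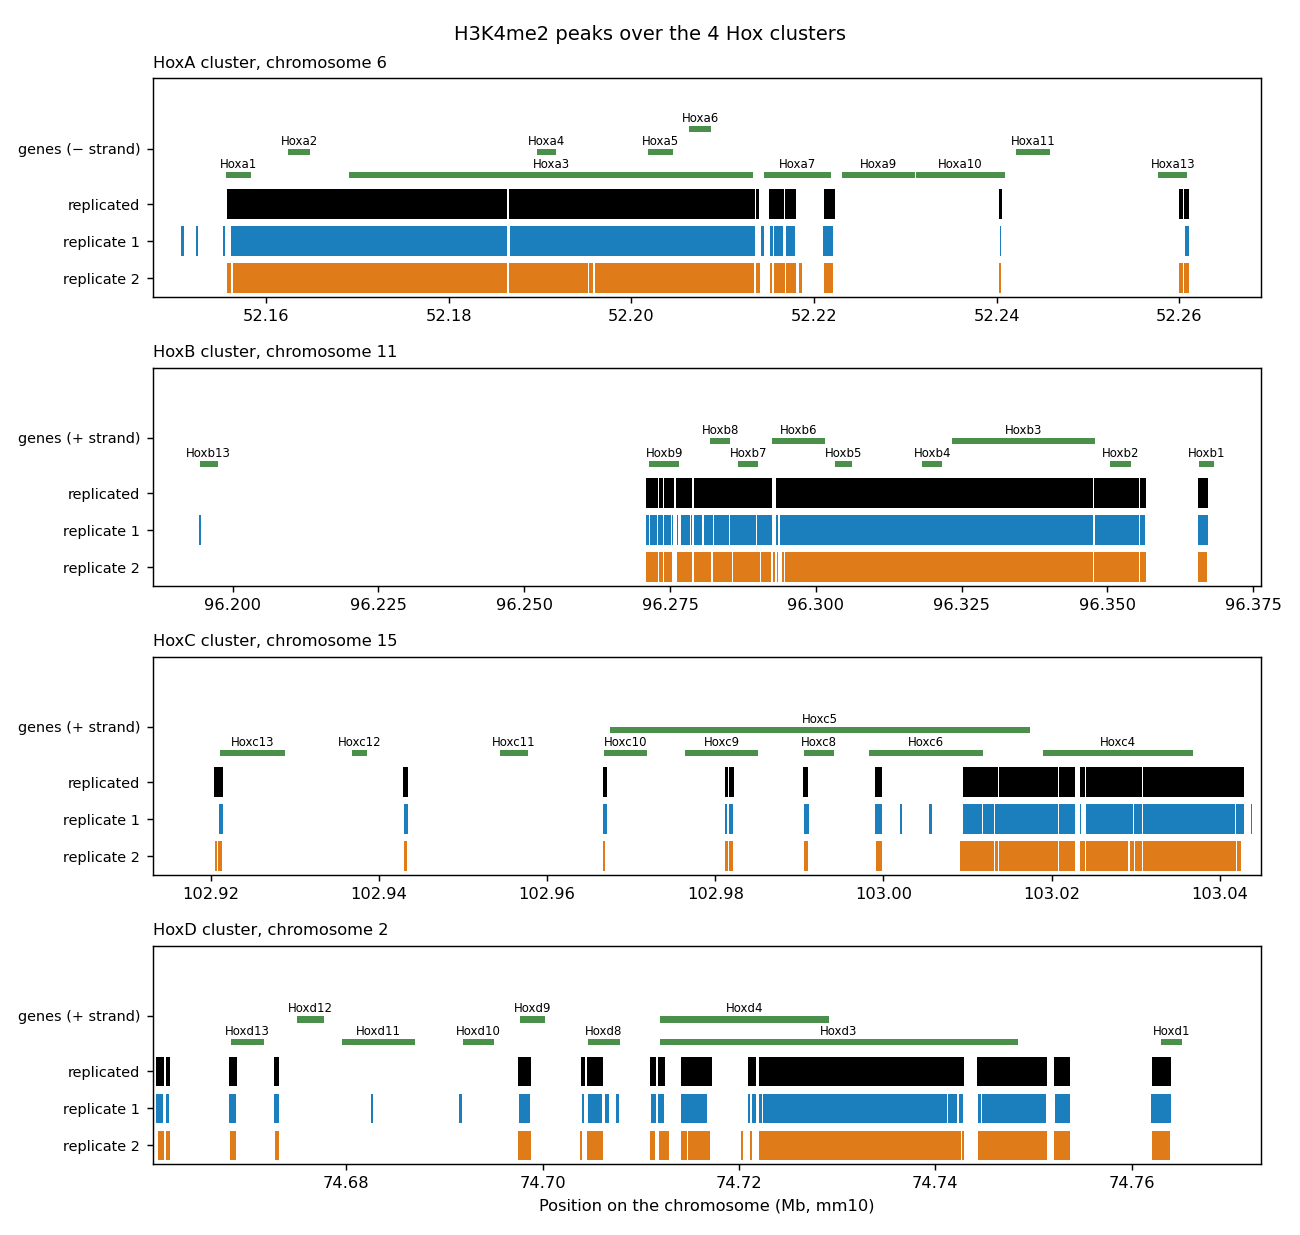
H3K4me2 peaks over the HoxA, HoxB, HoxC and HoxD clusters (x axis, position in Mb on mm10), with the replicated list and each replicate as filled boxes and the annotated extent of each Hox gene in green above. Peaks were nearly continuous from Hoxb9 to Hoxb2 (85.8 kb after merging) and from Hoxa6 to Hoxa1 (58.3 kb), and short over groups 9 to 13, where those at Hoxb9 joined the long domain only after merging.

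Listed hindbrain regulators carried longer domains on average than listed forebrain regulators. Whether a listed gene is restricted to its region was not tested. The mean was 11.9 kb at 32 hindbrain regulators and 1.80 kb at 22 forebrain regulators, a difference of 10.1 kb (95% interval 6.91 to 13.8 kb, two-sided permutation p = 2e-05, the smallest possible; medians 8.96 and 1.499 kb). Among genes of the midbrain-hindbrain boundary and rhombomeres, Meis2 had 31.7 kb (30.4 ± 1.78 kb in the replicates), Pax2 21.4 kb (21.2 ± 0.161 kb), Irx2 18.9 kb (17.0 ± 2.26 kb) and Meis1 17.3 kb (17.4 ± 0.101 kb). Among regulators of the rhombic lip, from which cerebellar granule cells arise, and of the cerebellum, Zic1 and Zic4 were followed by Pax6 at 22.5 kb (19.8 ± 3.85 kb) and by Lhx9 at 16.6 kb, although each replicate's own list split the Lhx9 domain and gave 8.18 ± 0.0382 kb. The longest forebrain domains were those of the chromatin organizer gene Satb2 at 4.82 kb, Sp8 at 4.31 kb, Lhx6 at 3.40 kb and Vax1 at 2.85 kb (1.67 ± 1.54 kb in the replicates). Quartiles were 8.08 and 15.5 kb in the midbrain-hindbrain boundary list and 3.88 and 15.3 kb in the rhombic lip list. In the forebrain list they were 0.775 and 2.54 kb. The lists overlapped. In the replicated list the hindbrain regulators Egr2 (4.435 kb), Ptf1a (4.04 kb), Wnt1 (4.02 kb) and Atoh1 (3.40 kb) had shorter domains than Satb2. So did Barhl2 (2.26 kb), Gdf7 (1.745 kb), Fgf8 (1.12 kb) and Barhl1 (0.781 kb). In the replicates Ptf1a had 2.97 ± 1.29 kb, Wnt1 2.78 ± 1.78 kb and Gdf7 5.03 ± 0.229 kb.

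All 16, 16 and 22 members of these 3 lists were marked in the replicated list (95.5% of forebrain regulators in the replicate 2 list). Some forebrain promoters carried weak peaks, among them Fezf2 and Tbr1 (fold 3.62 each), Rax (3.98) and Six6 (4.38). Others carried strong ones, such as Satb2 (55.1) and Dlx2 (42.4). At the hindbrain regulators Wnt1 and Skor2 the highest folds were 6.79 and 7.55. Extent was not tested apart from strength. The forebrain list was marked more often than other genes (adjusted p = 0.00185, Fisher's exact test), but its domain lengths were at a mean rank percentile of 49.4 (adjusted p = 0.918, permutation). Unmarked genes rank lowest in that test, and among marked genes alone the forebrain list was at 24.4, with shorter domains (adjusted p = 2.33e-05, permutation). Its promoter call was lost when peaks needed a −log10 q of 10 (81.8% marked, adjusted p = 0.21) or when the 5′ end alone was used (adjusted p = 0.149, both by Fisher's exact test). Without merging of peaks the difference between hindbrain and forebrain regulators was 4.95 kb (permutation p = 2e-05).

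**Figure D3:**
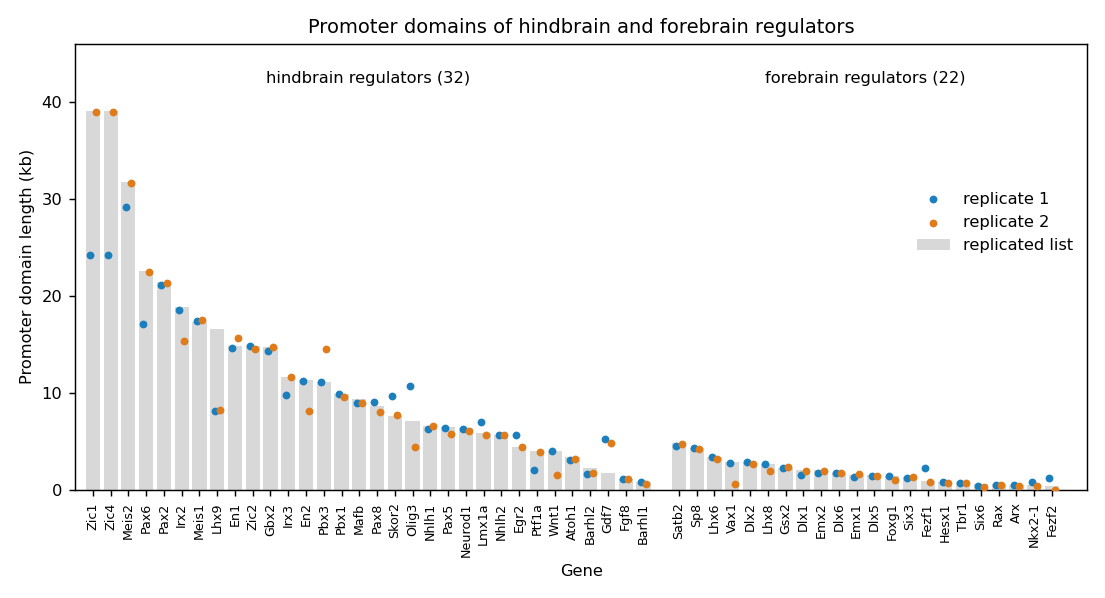
Promoter domain length in kb (y axis) at each of 32 hindbrain and 22 forebrain regulators (x axis, ordered by length), with the replicated list as bars and the 2 replicates as points. Forebrain regulators reached at most 4.82 kb (Satb2), and Zic1 and Zic4 were the longest hindbrain domains at 39.0 kb.

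Of the 24 gene lists, 11 were marked more often than other genes and 5 less often, and 11 had longer and 7 shorter domains than random lists. Neural progenitor genes were all marked (20 of 20) with a median domain of 7.62 kb (7.17 ± 0.416 kb in the replicates, n = 2), led by Sox2 (20.9 kb), Notch1 (20.7 kb), Nfia (14.5 kb) and the Notch ligand gene Dll1 (13.5 kb). Pan-neuronal genes were also all marked (16 of 16), with a median of 6.63 kb (6.75 ± 0.208 kb) and the highest mean rank percentile of the 24 lists, 94.96. Their longest domains were at the RNA-binding protein gene Elavl4 (15.4 kb), the neurofilament gene Nefm (9.55 kb; 8.21 ± 2.67 kb in the replicates), Stmn2 (8.73 kb) and the synaptic gene Nrxn1 (8.68 kb). Both lists had an adjusted p of 3e-05 for domain length, the smallest these permutation tests gave.

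The Sonic hedgehog pathway was marked at 12 of 12 genes with a mean rank percentile of 90.6 (adjusted p = 3e-05, permutation). The receptor gene Ptch1 had 27.2 kb (25.7 ± 2.13 kb in the replicates), Shh itself 10.004 kb (7.63 ± 3.50 kb), Boc 9.97 kb and Gli2 7.60 kb. Genes of the neural crest and sensory ganglia were marked at 12 of 12 and had a percentile of 79.9 (adjusted p = 0.00016, permutation), with Tfap2a (14.5 kb), Tfap2b (14.3 kb), the sensory neuron factor gene Pou4f1 (11.7 kb; 8.52 ± 4.12 kb in the replicates) and Foxd3 (11.3 kb). With the 5′ end alone the neural crest list lost both calls (adjusted p = 0.265 for the promoter by Fisher's exact test and 0.0837 for length by permutation). When receptor genes and chromosome Y were left out of the background, the promoter calls of both lists and of Hox groups 1 to 4 and 5 to 8 were lost, with 100% still marked (adjusted p = 0.0615, Fisher's exact test).

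Genes that set the transmitter of hindbrain neurons were marked at 19 of 22 (adjusted p = 0.0902, Fisher's exact test), and their domains were longer than those of random lists (percentile 64.7, adjusted p = 0.0188, permutation). Gata3 (21.4 kb) and Lmx1b (21.1 kb), needed for V2b interneurons and serotonergic neurons, the glutamate transporter gene Slc17a6 (16.3 kb, split to 4.71 ± 0.211 kb in the replicates' own lists) and the vesicular GABA and glycine transporter gene Slc32a1 (15.4 kb) were longest. The catecholamine enzyme genes Dbh, Ddc and Th were unmarked in the replicated list, but the replicate 2 list had short peaks at Ddc (0.185 kb) and Th (0.265 kb). The promoter call was gained with the pooled list (95.5% marked, adjusted p = 0.00539) and with replicate 2 alone (95.5%, adjusted p = 0.00512, both by Fisher's exact test), and the length call was lost under 4 alternatives, among them single peaks (percentile 61.6, adjusted p = 0.072, permutation) and marked genes alone (58.7, adjusted p = 0.221).

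Cell cycle genes (17 of 17) and housekeeping genes (16 of 16) were all marked, with percentiles of 71.4 and 77.5 (adjusted p = 0.00238 and 0.000131, permutation). Ccnd2 (7.79 kb), Ccnd1 (7.73 kb), Mki67 (4.11 kb) and Plk1 (4.07 kb) led the former, and the tubulin gene Tubb5 (10.1 kb), Rpl13a (8.66 kb; 6.29 ± 3.19 kb in the replicates), Ywhaz (7.845 kb) and Actb (6.25 kb) the latter. Among marked genes alone the cell cycle list no longer stood apart (percentile 57.2, adjusted p = 0.328, permutation).

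Glial lists did not differ from other genes at promoters. The oligodendrocyte lineage was marked at 9 of 13 genes (adjusted p = 1, Fisher's exact test). Pdgfra (8.83 kb), Sox10 (6.07 kb), Nkx2-2 (5.68 kb) and Cspg4 (3.66 kb) had the longest domains in the replicated list. Cspg4 had 1.85 ± 0.0134 kb in the replicates, where Olig2 and Mbp were longer. The myelin genes Mag, Mobp, Mog and Plp1 were unmarked in the replicated list, with a short Mobp peak in replicate 1. Astrocyte genes were marked at 8 of 11 (adjusted p = 1, Fisher's exact test), among them Fgfr3 (8.48 kb), the glutamate transporter gene Slc1a2 (7.28 kb), Sparcl1 (7.23 kb) and Glul (5.22 kb). Aqp4, Gfap and S100b, which mark mature astrocytes, were unmarked. Their domain lengths did not pass the test either (adjusted p = 0.62 for the oligodendrocyte lineage and 0.0901 for astrocytes, permutation).

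Markers of other cells that a dissected hindbrain could hold fell into groups. Endothelial genes were marked at 10 of 13 and mesenchymal, meningeal and pericyte genes at 12 of 14, neither different from other genes (adjusted p = 0.616 and 0.197, Fisher's exact test). Esam (4.595 kb), Egfl7 (3.36 kb), Cldn5 (3.26 kb; 2.87 ± 1.59 kb in the replicates) and Kdr (2.46 kb) were the longest endothelial domains, with Emcn, Tek and Tie1 unmarked (Tek had a short peak in replicate 1). Pdgfrb (5.57 kb), Prrx1 (4.55 kb; 5.51 ± 2.09 kb), Foxc1 (3.30 kb; 3.59 ± 1.17 kb) and Twist1 (3.01 kb) were the longest mesenchymal ones, with Col3a1 and Lum unmarked. Choroid plexus genes were marked at 7 of 12 (adjusted p = 0.616, Fisher's exact test), with Msx1 (8.08 kb), Foxj1 (5.07 kb), Enpp2 (3.42 kb) and Kl (1.89 kb) longest. Aqp1, Cldn2, Folr1, Kcne2 and Ttr were unmarked, apart from short peaks at Aqp1 and Kcne2 in the replicate 1 list. The domain lengths of these 3 lists did not pass the test (adjusted p = 0.813, 0.551 and 0.415, permutation).

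Erythroid genes (4 of 14 marked), myeloid genes including microglial ones (1 of 13), liver genes (2 of 12), germ line genes (2 of 13) and olfactory and vomeronasal receptors (4 of 1463) were marked less often than other genes. The adjusted p-values of the first 4 were 0.00755, 0.000185, 0.00202 and 0.00157 (Fisher's exact test). Promoter CpG ratio bears on these calls: genes matched on it were marked as rarely as the erythroid list (4 against a mean of 3.81, adjusted permutation p = 0.717), and the myeloid and liver lists were undecided (adjusted permutation p = 0.124 and 0.0789). The germ line list was marked less often than matched genes (2 against 8.37, adjusted permutation p = 4.0e-05). Matched genes were drawn from all other genes, with the receptor genes among them. The erythroid genes with a peak were the regulators Tal1 (9.72 kb), Klf1 (1.53 kb) and Nfe2 (1.00 kb) and the glycophorin gene Gypa (1.68 kb), and none of the listed globin genes was marked. P2ry12 (0.635 kb; 0.433 ± 0.0728 kb in the replicates) was the marked myeloid gene, Foxa3 (2.30 kb) and Apoa1 (1.46 kb, with no replicate 1 peak within 1 kb of a TSS) the marked liver genes, and Dazl and Dmc1 (1.07 kb each) the marked germ line genes. The marked receptor genes were Vmn1r4 (3.22 kb), Olfr94 (1.66 kb), Olfr658 (0.494 kb) and Olfr1033 (0.415 kb). Muscle genes were marked at 6 of 14, with Myod1 (2.43 kb), Hand2 (1.43 kb), Myf6 (1.09 kb) and Des (0.979 kb) longest (adjusted p = 0.106, Fisher's exact test). These 6 lists and Hox groups 9 to 13 (7 of 16, adjusted p = 0.0875, Fisher's exact test) were the 7 with shorter domains. Most of their members are unmarked and enter as length 0, so this restates how few were marked and is not a separate result. None of the 7 had the 10 marked members needed for the test among marked genes. The highest adjusted p among them was 0.00346, for the erythroid list and for Hox groups 9 to 13 (permutation).

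**Figure D4:**
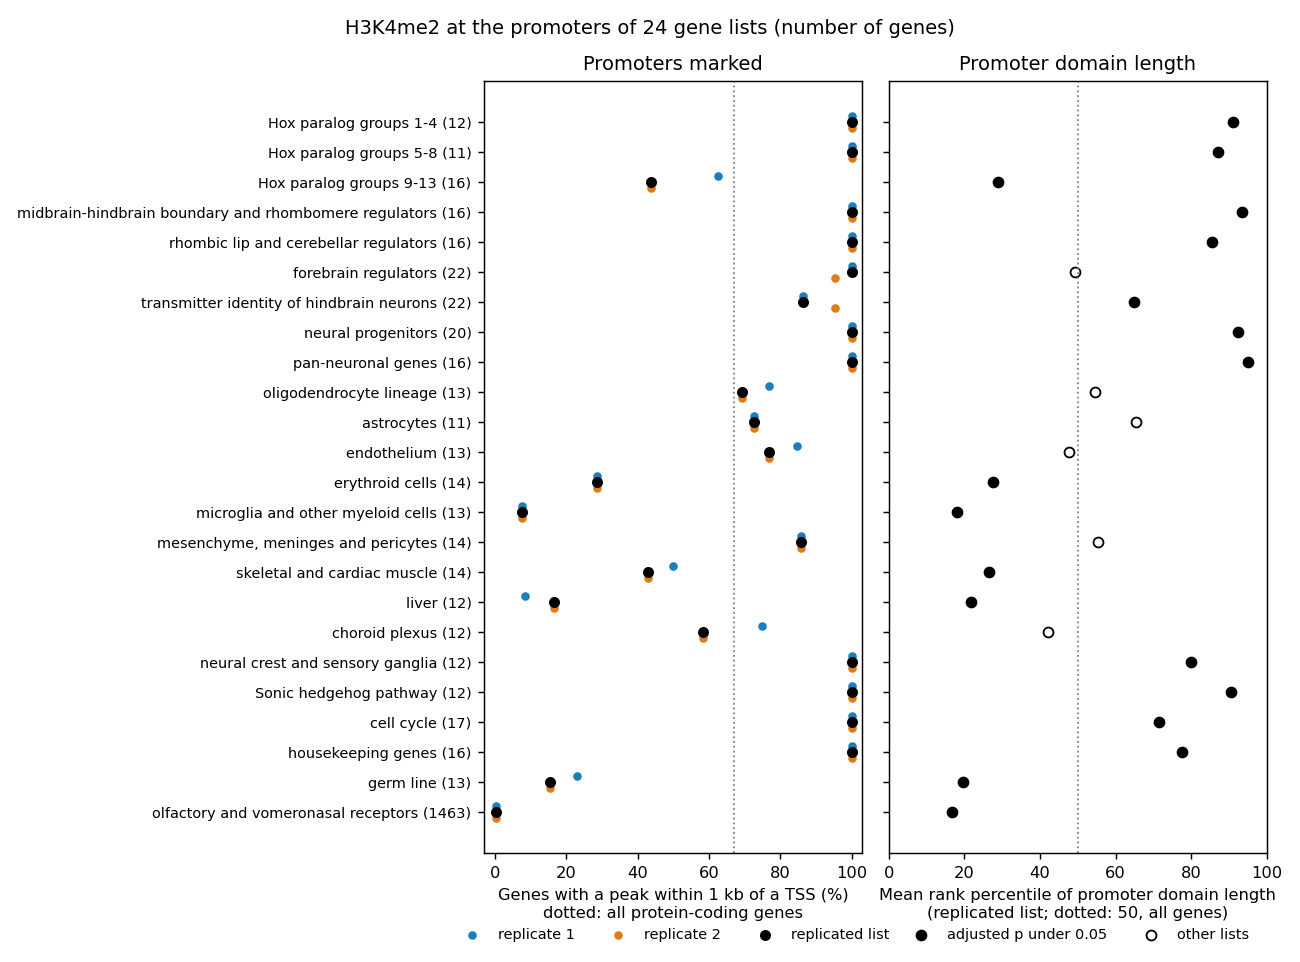
Left, percentage of each list's genes with an H3K4me2 peak within 1 kb of a TSS (x axis) in the replicated list and in each replicate, with the 66.9% of all protein-coding genes dotted. Right, mean rank percentile of promoter domain length (x axis), filled where the adjusted permutation p was under 0.05, with pan-neuronal genes highest at 94.96 and receptor genes lowest at 16.6.

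Distal peaks made up 51.8% of the replicated peaks (19749 of 38099; 55.9% ± 0.185 in the replicate lists, n = 2). As only protein-coding TSSs were used, they can include promoters of non-coding genes. The genes with the most distal peaks were the homeodomain and zinc finger gene Zfhx3 (40; 63 ± 1.41 in the replicate lists), the latrophilin gene Adgrl2 (37), the predicted gene Gm11146 (37), Gse1 (37; 57 ± 9.90), Auts2 (36), Zfp608 (34; 48.5 ± 7.78), Nr2f2 (28), Zfp536 (26), Ebf1 (25) and the Notch coactivator gene Maml3 (25).

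By list, 11 had more distal peaks than random lists and the receptor genes had fewer (adjusted p = 2.4e-05, permutation). Of the distal peaks 2099 lay inside a promoter domain, so these counts are not fully separate from domain length. The list tests were not repeated without those peaks. By nearest TSS the highest mean rank percentile was that of midbrain-hindbrain boundary and rhombomere regulators at 95.5, with a median of 9.5 distal peaks per gene against 0 over all genes. Rhombic lip regulators (86.5), neural progenitors (85.2), neural crest genes (84.6), Sonic hedgehog genes (83.0), pan-neuronal genes (81.8), the oligodendrocyte lineage (80.4), mesenchymal genes (79.99) and forebrain regulators (77.6) followed, all with an adjusted p of 2.4e-05, the smallest these permutation tests gave. Transmitter identity genes were at 67.1 (adjusted p = 0.00242) and endothelial genes at 65.3 (adjusted p = 0.0383, both by permutation).

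Cell cycle and housekeeping genes, whose promoters were all marked, did not have more distal peaks (percentiles 48.6 and 54.0, adjusted p = 0.848 and 0.592, permutation). The count depends on the distance to neighbouring genes, and crowded clusters such as the Hox genes can hold few peaks as the nearest TSS. When peaks within 50 kb of a TSS were counted in its place, all 3 sets of Hox genes gained a call for more distal peaks: groups 1 to 4 moved from 54.2 to 68.3 (adjusted p = 0.033), groups 5 to 8 from 40.0 to 70.3 (adjusted p = 0.0223) and groups 9 to 13 from 41.0 to 76.8 (adjusted p = 0.00016, all by permutation). Under this rule a peak counts for every gene with a TSS within 50 kb. Neighbouring Hox genes therefore count the same peaks, while the test treats them as independent. Rhombic lip regulators (94.96) and neural crest genes (90.2) then ranked above the midbrain-hindbrain boundary and rhombomere list (87.2), and the mesenchymal list lost its call (62.4, adjusted p = 0.128, permutation). Endothelial genes lost theirs under 3 alternatives, with adjusted p from 0.0629 to 0.10 (permutation).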

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

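Signal outside the 21 chromosomes drew attention because no comparison used it: 15 replicated peaks lay on 6 unplaced or unlocalised contigs. Their median fold was 6.95 and their median width 711 bp, and each replicate's own list held 16 such peaks.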

How the results depend on the processing

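Counting a shared Hox domain once within its group and leaving out Hoxb9 were chosen after the data were seen. Over the alternatives run, the main values stayed the same in 101 comparisons and moved in 3. A count of lists was taken as the same within 1.5 times its main value, so the 11 lists with more distal peaks could become 10 or 12. The difference between hindbrain and forebrain regulators ranged from 4.95 to 10.5 kb and that of Hox domain lengths from 23.8 to 47.3 kb, with permutation p of at most 0.0479. Leaving out 1 replicate at a time gave 8.79 to 9.80 kb and 42.1 to 43.5 kb. Without receptor genes and chromosome Y, 7 lists in place of 11 were marked more often and 0 in place of 1 had fewer distal peaks. The receptor list itself is then absent, and the share marked among the remaining genes is higher. Among genes with a promoter peak alone, 1 list in place of 7 had shorter domains. The 7 could not be tested there, as only the 14 lists with at least 10 marked members were. The 1 list was the forebrain regulators, at a percentile of 24.4 (adjusted p = 2.33e-05, permutation). For single lists and annotation classes 677 values were the same, 17 lost and 8 gained their call, and 5 reversed. Those 5 were the distal percentiles of Hox groups 5 to 8 (70.3) and 9 to 13 (76.8) with peaks within 50 kb of a TSS, the exon ratio within 2.5 kb (still above 1, at 1.01, but with 2.08% of covered bases below the 2.24% of shifted lists), and the intron ratio of 1.22 within 500 bp and of 1.12 with the 5′ end alone. In the Hox reversals neighbouring genes counted the same peaks, each of which the nearest-TSS rule gives to a single gene. Whether this was the cause was not tested. The ratios follow from which bases near a TSS count as promoter. Hox groups 9 to 13 were marked less often with −log10 q of at least 10 (31.2%, adjusted p = 0.0136) and without receptor genes and chromosome Y (43.75%, adjusted p = 0.0394, both by Fisher's exact test). Astrocyte genes gained a call for more distal peaks with the pooled list (adjusted p = 0.0324) and with replicate 2 alone (adjusted p = 0.0442, both by permutation). Every alternative named under the methods was run, but not for every result. The comparisons of hindbrain with forebrain regulators and of Hox groups were not run with other TSS windows, the 5′ end alone or other backgrounds. Their ranges above do not cover those settings. Unknown depth limits what the absence of a weak or distal peak shows.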

Other observations

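The tests of miRNA genes, of gene families, of the CpG ratio for each list alone and of distal peaks inside promoter domains were chosen after the results were seen. Of the 219 domains of 10 kb or more, 17 reached no protein-coding promoter, and several lay over miRNA genes of the nervous system. The longest, 30.01 kb on chromosome 13 (83712937 to 83742947; 30.01 ± 0.00354 kb covered in the replicate lists, n = 2), held Mir9-2. Domains of 28.4 kb on chromosome 3 and 26.5 kb on chromosome 7 held Mir9-1 and Mir9-3, so all 3 genes for miR-9, a miRNA of neural progenitors, lay under such domains. Mir124a-2 (19.0 kb, chromosome 3) and Mir124a-1 (15.1 kb, chromosome 14), which encode the neuronal miR-124, and Mir125b-1 (13.4 kb, chromosome 9) did too. In all, 6 of the 17 domains held an annotated miRNA gene, against a mean of 0.2 and at most 2 in 100 shifts, so random position is argued against (permutation p = 0.0099, the smallest possible). The shifted positions were not matched for transcription, so the test does not separate miRNA genes from other transcribed loci. Each of the 6 domains also held other non-coding genes, among them Mir9-3hg, Mir124-2hg and Mir124a-1hg. Another domain of 10.9 kb on chromosome 19 covered the long non-coding RNA gene Malat1. Over 5 kb from a coding TSS, 13.6% of 5197 lincRNA genes were marked (14.2% ± 0.259 in the replicates), as were 13.4% of 1611 antisense genes and 6.41% of 1670 miRNA genes.

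By symbol stem, 269 protein-coding gene families had 10 or more members, of which 85 had longer and 62 shorter domains than 20000 random lists (adjusted permutation p under the threshold). Unmarked genes enter as length 0, so both counts partly reflect the share of members marked. Where most members of a family are unmarked, a call of shorter domains restates how few were marked. The Wnt receptor genes (Fzd) were all marked, with a median domain of 5.70 kb (5.84 ± 0.455 kb in the replicates, n = 2) and the highest mean rank percentile, 88.4. The protocadherins outside the clusters (stem Pcdh) had a median of 7.72 kb (7.83 ± 0.364 kb), while clustered ones differed: 8.33% of Pcdha and 4.55% of Pcdhb genes were marked (percentiles 18.5 and 17.3, adjusted permutation p = 0.000224), and 100% of Pcdhga genes, with a median of 0.815 kb against 2.83 kb at all marked promoters. Their rank among all genes did not pass the test (percentile 37.8, adjusted permutation p = 0.195), in which unmarked genes rank lowest. Sox genes had a median of 6.58 kb (6.64 ± 0.168 kb), the chromatin regulators Arid 6.05 kb and Chd 4.47 kb, and the axon guidance Semaphorin genes 4.53 kb. None of the members of the beta-defensin (Defb, 42 genes), secretoglobin (Scgb, 34) and reproductive homeobox (Rhox, 34) families were marked (0%).

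Fewer marked promoters in the erythroid, myeloid, liver and germ line lists (9 of 52 genes) could have a technical source. Reads lost at near-identical gene copies are argued against as the sole source. Globin, C1q, fibrinogen, Serpina1, Apo, Prm and Tnp genes were left out by symbol, and how alike their sequences are was not tested. Of the 34 other members 8 were marked, still less often than the 67.0% of other genes (p = 2.59e-07, Fisher's exact test). CpG-poor promoters account for part: genes matched on CpG ratio were marked 20.7 times out of 52 on average (one-sided permutation p = 2.0e-05), and 12.3 times against 7 without the germ line list (p = 0.0228). For each list alone, by permutation, erythroid genes were marked as often as matched genes (4 against 3.81, adjusted p = 0.717) and germ line genes less often (2 against 8.37, adjusted p = 4.0e-05), while for myeloid (1 against 3.44, adjusted p = 0.124) and liver genes (2 against 5.05, adjusted p = 0.0789) the CpG ratio cannot be told apart from a further difference at these list sizes. The matched genes were drawn from all other genes, including the rarely marked receptor genes, which can lower the number expected. The CpG ratio was taken at the 5′ end of each gene alone. No biological explanation was tested, as the design holds no second tissue.

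Longer domains at hindbrain than at forebrain regulators were not accounted for in full by the technical explanations tested, although merging accounted for part of the size. With labels permuted within 5 bins of CpG ratio the difference remained (permutation p = 1.0e-05, the smallest possible), and the median CpG ratios were 0.686 and 0.644. With single peaks in place of merged domains the means were 6.47 and 1.52 kb (permutation p = 2.0e-05). The difference was 4.95 kb, against 10.1 kb with merged domains. Without genes whose domain reached another gene's promoter, 30 hindbrain and 20 forebrain genes had means of 10.1 and 1.88 kb (permutation p = 2.0e-05). A candidate explanation is the region dissected, which stays a hypothesis, since no forebrain sample was compared.

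Peaks found in the list of only 1 replicate are consistent with weak peaks near the calling threshold: among the 50% of peaks with the smallest p, at most 0.079% had no partner in the other list. Depth, which is unknown, stays open.

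Domain length rose with the number of distal peaks across 14625 marked genes (Spearman's rho 0.257; 0.309 and 0.317 in the replicates; genes are not independent). Part of this was built in, as 2099 distal peaks belonged to a promoter domain and counted on both sides, and without them rho was 0.162. Gene-poor surroundings were examined within 10 bins of distance to the nearest other TSS. There the median rho was 0.249 with all distal peaks and 0.135 without those 2099, the latter ranging from -0.0214 to 0.367. That distance takes the closer side of a gene only, while distal peaks are collected on both sides. The test therefore cannot decide whether gene-poor surroundings are the source.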
